A study of Homo sapiens with 6 samples.

How the data were processed

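The data were 6 lists of ATAC-seq peaks, 1 for each library of day-15 ventricular-like cardiomyocytes differentiated from the H9 embryonic stem cell line, with 3 control and 3 ZNF436 knockdown libraries. Per the labels' protocols, the replicates were independent differentiations. Per the submitters' processing notes, Bowtie2 2.4.5, bedtools 2.30.0 and the genome build hg19 were used. The role and order of these tools are not given in the sources used here. Each deposited list gives a peak's chromosome, start, end, name and an integer score. The peak names begin with MACS and carry the name of 1 library, so that peaks appear to have been called per library. The version of the caller, its threshold, and any shift for the Tn5 cut or removal of duplicates are not given in the sources used here. The score is the peak caller's own value in the authors' lists, with a lowest value between 20 and 25 in each. It was used only to rank peaks within a list.

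The lists give no read counts and no depth, so the depth of each library is unknown. The number of peaks a caller reports rises with depth and with signal over background, and neither could be separated from the group here. The tests of peak numbers, covered bases, regions, similarity and bins were fixed before the data were examined. The tests on flanks, the tests of explanations in the closing section and a few alternatives named there were chosen afterwards. The number of peaks and the bases they cover were compared by an exact permutation test of 3 against 3 libraries, two-sided, whose smallest possible p is 0.1. Peaks of all libraries that overlapped by at least 1 bp were merged into regions. A region counted as called in a library when a peak of that library overlapped it. Regions called in all 3 libraries of 1 group and in none of the other were counted, as were those of the other 18 choices of 3 libraries. Similarity was the Jaccard index of covered bases, compared within and between groups over the 10 splits of the libraries, one-sided.

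The test planned for genes was run on fixed bins of 1 Mb, as written beforehand for the case that no annotation of hg19 is used. Peaks were counted per bin by their midpoint and turned into log2((peaks + 0.5) / library total × median total). Bins with a mean of at least 2 peaks over the 6 libraries entered limma 3.58.1 with trended and robust variance estimation, in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. On simulated counts for knockdown against control with 2807 tested bins, limma called 71% of bins changed 2-fold, 94% of those changed 3-fold and 0.31% of unchanged bins. The simulated changes lay only in bins with more control peaks than any of the named rises had. The spread was fixed, and unchanged bins followed the list length evenly. These rates therefore do not apply to sparsely filled bins or to uneven effects of list length. The counting of regions was also tested on simulated data. All else was computed in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.

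The regions named are those called in 1 group only, up to 5 per direction, whose lowest score percentile in the 3 lists was highest. The rule written for genes was applied to bins in their place. It takes up to 10 largest rises and 10 largest falls among bins under the adjusted p threshold whose 3 knockdown values did not overlap the 3 control values. By chance, 10% of bins would have separate groups. The named bins are ordered by change.

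The longest stretch without a peak in any library was found for each of chromosomes 1 to 22 and X, and the 3 Mb on both sides were called its flanks. The flanks were defined after the data were seen, and their definition was changed once after results under it had been seen. The stretch was first sought between the first and the last peak of a chromosome, which on some chromosomes gave stretches of as little as 0.5 Mb. It was then sought from the first base, which gave 3.0 to 21.05 Mb. Values under both definitions are given in the closing section, and the report uses the second.

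The alternatives were the stronger part of each list, lists of equal length by score (ties broken at random with a fixed seed) or by random thinning, autosomes and X only, other overlap and merging rules, other pseudocounts, filters and scalings, the replicate number as a block, and leaving out each library. The planned promoter share, gene lists, share of repeat bases and motifs need an annotation or sequence of hg19 and were not analysed here. The gene table at hand has coordinates of another build and was not used here. The planned test of read counts does not apply to peak lists.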

Results

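Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in ventricular-like cardiomyocytes made from the human embryonic stem cell line H9. The cells were taken at day 15 of differentiation from control cultures and from cultures with knockdown of ZNF436, a KRAB zinc finger protein. Each group had 3 libraries, which per the labels came from independent differentiations. The series design states that gene expression, histone marks and accessibility were compared between these conditions. The title of the series places that comparison in the control of transposon-derived regulatory elements. The values used here were 1 list of called peaks per library, with positions on hg19. The sequencing depth of the libraries is unknown here, so no value below could be corrected for it. The locus of ZNF436 was not analysed here, so the knockdown itself was not checked.

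Knockdown cells had more called accessible sites than control cells. The control libraries held 50719, 53662 and 68342 peaks (replicates 1, 2 and 3) and the knockdown libraries 115864, 102454 and 87871. The mean was 57574 ± 9440 peaks in control and 102063 ± 14001 in knockdown (SD, n = 3 each; exact permutation test, two-sided, p = 0.1), a ratio of 1.773 ± 0.379. The covered bases followed, with 23.7 ± 3.18 Mb in control and 43.9 ± 5.36 Mb in knockdown (SD, n = 3 each; exact permutation test, two-sided, p = 0.1). The lowest knockdown library had 1.286 times the peaks of the highest control library. With 3 libraries against 3, 0.1 is the smallest p this test can give, so neither difference could pass a threshold of 0.05. The median peak width was 280 ± 9.61 bp in control and 297 ± 8.19 bp in knockdown (SD, n = 3 each; exact permutation test, two-sided, p = 0.2).

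**Figure D1:**
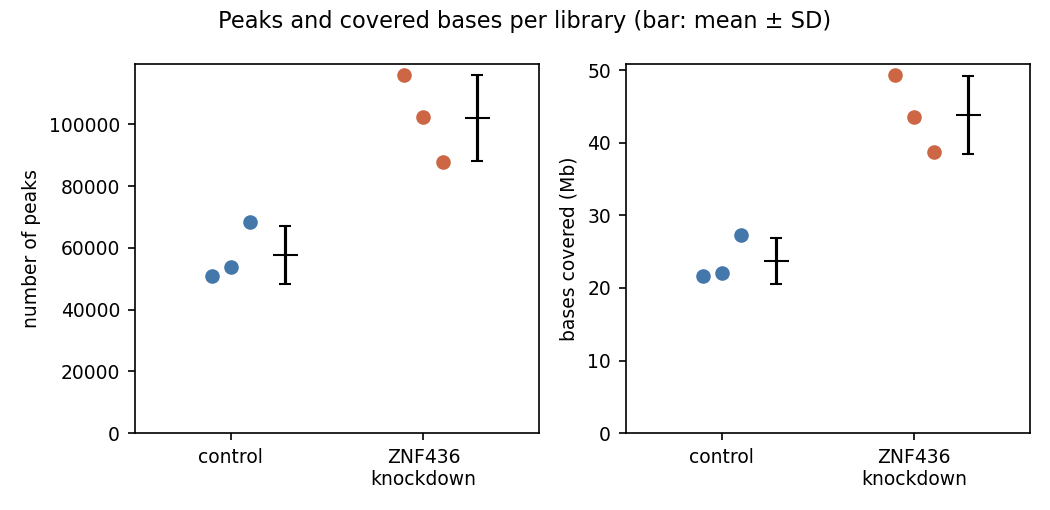
Number of peaks (left) and bases covered in Mb (right) for each library, with points for single libraries and a bar for the mean ± SD of the 3 libraries of a group. All 3 knockdown libraries lay above all 3 control libraries, with a mean of 102063 peaks against 57574.

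The sites called in a single group lay mostly on the knockdown side. The union of all peaks held 157560 regions, of which 28749 (18.25%) were called in all 6 libraries and 60349 (38.3%) in 1 library only. Of the rest, 12157 regions were called in all 3 knockdown libraries and in no control library, and 207 in all 3 control libraries and in no knockdown library. For the other 18 ways to pick 3 of the 6 libraries the count ran from 48 to 1775, and 7 of them gave at least the 207 of the control libraries. Regions called only in knockdown had a median width of 353 bp, those called only in control 392 bp and those called in all 6 libraries 873 bp.

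Among the regions called only in knockdown, the peak scores ranked highest within their own lists at chromosome 5:161495566-161495827, chromosome 11:85904645-85904899, chromosome 4:143269798-143270169, chromosome 5:167870696-167871575 and chromosome 1:88646233-88646608. The lowest of the 3 score percentiles was 85.46 for the first of these and 82.91 for the last. It was 70.64 and 69.68 with lists of equal length by score, in which only stronger peaks remained to rank against. Among the regions called only in control they were chromosome 22:18879940-18880094, chromosome 17:122808-123095, chromosome 19:54637227-54637517, chromosome 19:16044700-16044886 and chromosome 2:132769868-132770041. Here the lowest percentile ran from 93.69 on chromosome 22 to 69.09 on chromosome 2 (93.23 and 67.29 with lists of equal length). The region on chromosome 22 lay within 3 Mb of the longest stretch of that chromosome without a peak in any library. No gene annotation of hg19 was used here, so these regions are given by position alone.

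This difference depended on the length of the lists. With the 50719 strongest peaks of each list, 2628 regions were called only in knockdown and 1113 only in control, against 108 to 593 for the other 18 choices of 3 libraries. With each list thinned at random to that length, 1894 regions were called only in knockdown and 2761 only in control. Thinning kept 43.8, 49.5 and 57.7% of the knockdown lists and 100, 94.5 and 74.2% of the control lists, which by itself lowers the count for knockdown. Cutting by score kept the same shares, so that lower ranks stayed in for control than for knockdown. Leaving out control replicate 3 gave 20491 regions called only in knockdown and leaving out knockdown replicate 3 gave 23412. Fewer libraries then had to meet the condition, but leaving out others raised the count less. It was 13999 and 14027 without control replicates 1 and 2, and 14514 and 17012 without knockdown replicates 1 and 2. Control replicate 3 called 8315 of the 20472 regions found in all 3 knockdown libraries and in neither other control library. With lists of equal length by score the counts for knockdown and control were 5456 and 3266 without control replicate 3, and 4677 and 1487 without knockdown replicate 3. Those for control were 1779 and 1839 without control replicates 1 and 2.

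**Figure D2:**
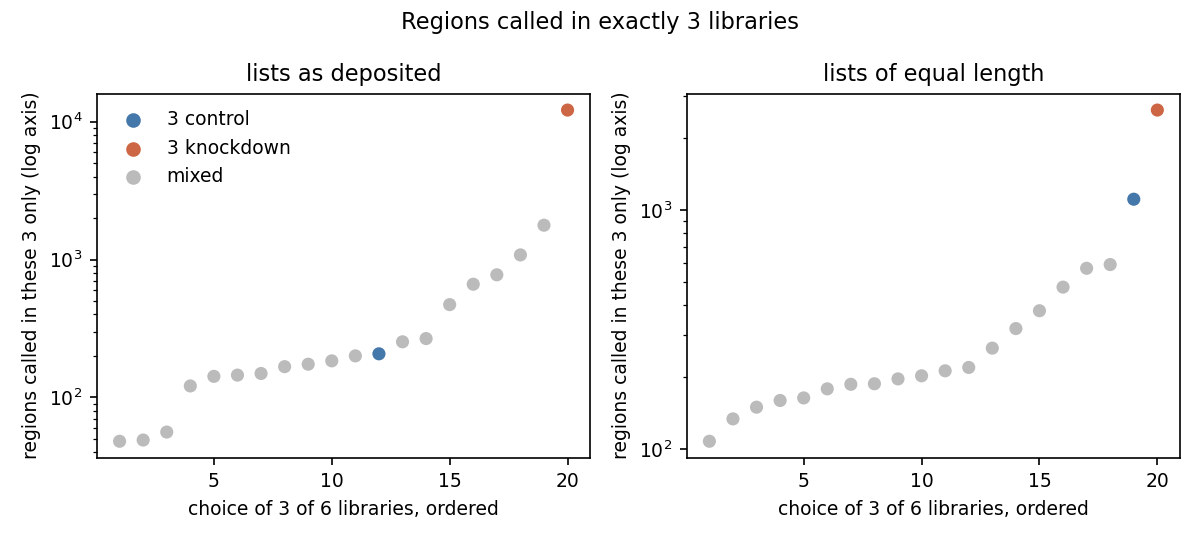
Regions called in exactly 3 libraries, for each of the 20 choices of 3 of the 6 libraries in rising order (log axis), with the lists as deposited (left) and with the 50719 strongest peaks of each list (right). The 3 knockdown libraries gave the highest count on both sides (12157 and 2628), while the 3 control libraries rose from 207, among the mixed choices in grey, to 1113, above all of them.

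On average, libraries were more alike within a group than between groups. The Jaccard index of covered bases averaged 0.568 among knockdown libraries, 0.503 among control libraries and 0.414 between the groups. The mean within groups exceeded that between groups by 0.121, with an SD of 0.04 over the 6 pairs within groups. The real grouping gave the highest of the 10 splits of the libraries (exact permutation test, one-sided, p = 0.1, the smallest possible), and the next split reached 0.018. Control replicate 3 stood nearest to the other group, with indices of 0.434, 0.474 and 0.494 to the knockdown libraries against 0.505 and 0.481 to the other control libraries. Without it, the difference was 0.169. The index of a pair of lists cannot exceed the ratio of their covered bases, so the longer knockdown lists can by themselves lower it between groups. With lists of equal length by score, the means were 0.586 within and 0.493 between groups. Their difference was 0.093, with an SD of 0.065 over the pairs within groups, again the highest of the 10 splits.

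The added peaks were not spread evenly along the chromosomes. In bins of 1 Mb, compared as shares of each library's peaks, 571 of 2856 tested bins were higher in knockdown and 292 were lower (limma, Benjamini-Hochberg adjusted p under 0.05). Chromosome 19 had 49 of its 58 bins lower and 0 higher, with 24 lower and 0 higher for lists of equal length, whereas without scaling to the library total 18 were higher and 1 lower. On chromosome 22, 9 of 36 bins were lower and 1 higher, and 17 were lower and 0 higher when scaled to the median ratio over bins, whereas without scaling 33 were higher and 1 lower. Chromosome 18 had 27 of 76 bins higher and 1 lower, which became 15 and 2 when scaled to the median ratio and 13 and 3 for lists of equal length. Chromosome 4 had 48 of 189 bins higher and 6 lower, which became 21 and 12 when scaled to the median ratio. Without scaling, 2564 bins of the genome were higher and 20 lower, so that the unscaled counts follow the longer knockdown lists.

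The median change over all bins was 0.16 on the log2 scale of (peaks + 0.5) per library total, and the changes of single bins are given relative to it. Bins that gained the largest share lay on chromosomes 4, 6, 8, 12 and 16. Chromosome 4:29000001-30000000 held 8.33 ± 1.15 peaks in knockdown against 0.33 ± 0.58 in control (SD, n = 3 each), a relative log2 change of 2.62 (limma adjusted p = 0.00292), which was 1.92 with a pseudocount of 1 and 3.22 without control replicate 1. Chromosome 8:31000001-32000000 held 14.67 ± 3.79 against 1 ± 1 peaks, a relative change of 2.60 (limma adjusted p = 0.00201), which was 3.19 without control replicate 1 and 2.02 without control replicate 2. Chromosome 6:68000001-69000000 had 0 peaks in each control library and 9, 5 and 4 in the knockdown libraries. Its relative change was 2.64, and 1.78 with a pseudocount of 1. The other 7 of the 10 largest rises were chromosome 16:61000001-62000000, chromosome 4:27000001-28000000, chromosome 4:136000001-137000000, chromosome 4:98000001-99000000, chromosome 12:86000001-87000000, chromosome 12:87000001-88000000 and chromosome 6:51000001-52000000. All 10 held a mean of 0 to 2 peaks in control, so the size of their change depends on the pseudocount. With lists of equal length, only chromosome 4:29000001-30000000 and chromosome 4:27000001-28000000 had enough peaks for a test. Their relative changes were then 2.62 and 1.94.

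Bins that lost the largest share lay mostly beside the longest stretch of their chromosome without a peak in any library. Chromosome 13:19000001-20000000 held 0.33 ± 0.58 peaks in knockdown against 6 ± 1.73 in control (SD, n = 3 each), a relative log2 change of -4.13 (limma adjusted p = 0.000385), which was -3.41 with a pseudocount of 1. Chromosome 15:22000001-23000000 held 38.33 ± 14.43 against 80.67 ± 10.02 peaks, a relative change of -2.11 (limma adjusted p = 0.000872), which was -3.50 with lists of equal length. Chromosome 22:16000001-17000000 held 1.67 ± 1.15 against 8.67 ± 3.06 peaks, a relative change of -3.14 (limma adjusted p = 0.000561). The other 7 of the 10 largest falls were chromosome 7:63000001-64000000, chromosome 7:57000001-58000000, chromosome 14:106000001-107000000, chromosome 18:14000001-15000000, chromosome 16:32000001-33000000, chromosome 19:27000001-28000000 and chromosome 1:142000001-143000000. Of these 10 bins, only that on chromosome 14 was not within 3 Mb of such a stretch, and that on chromosome 13 was not either when the stretch was sought from the first peak. With lists of equal length, the bins on chromosomes 14 and 18 did not stay under the threshold. Those on chromosome 13 and at chromosome 7:63000001-64000000 then had too few peaks for a test. Over all 292 lower bins, 61 had fewer peaks in knockdown than in control and 231 had as many or more, so that only their share of the library was lower. Of the 61, 46 lay within 3 Mb of the longest stretch without a peak and 15 did not (45 and 16 when sought from the first peak).

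The balance of higher and lower bins followed the scaling. Scaled to the median ratio over bins, 305 were higher and 446 lower, against 2564 and 20 with no scaling. All 305 higher bins under median scaling were among the 571, and all 292 lower bins were among the 446. Median scaling only shifted each library as a whole, which moved the median change from 0.16 to 0.025. Such a shift nearly fixes this nesting, so the nesting is no separate support. With lists of equal length, 369 bins were higher and 186 lower, of which 240 and 149 were shared with the lists as deposited and 0 were opposite. Leaving out 1 knockdown library also reduced the calls, to 135 higher and 159 lower without replicate 1, to 273 higher without replicate 2 and to 283 higher without replicate 3.

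**Figure D3:**
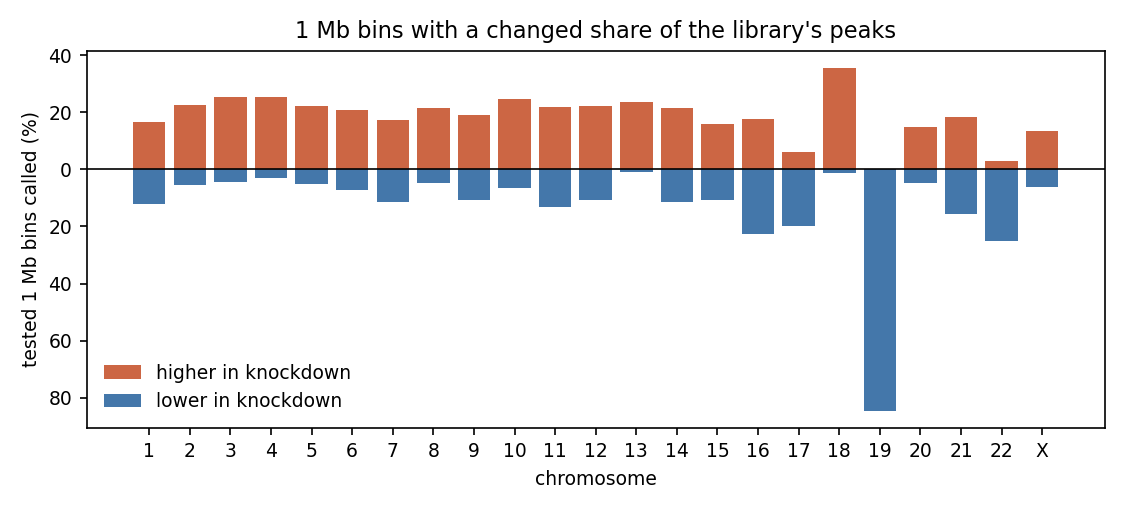
Percent of the tested 1 Mb bins of each chromosome whose share of the library's peaks was higher (upward bars) or lower (downward bars) in knockdown, by limma with an adjusted p under 0.05. Chromosome 19 had 84.5% of its bins lower and chromosome 18 had 35.5% higher, while without scaling to the library total chromosome 19 had 18 bins higher and 1 lower.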

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

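Bins outside the flanks, equal lists with median scaling and peaks covering at least 50% of a region were alternatives chosen after seeing the data. The peak ratio stayed between 1.653 and 1.956 and the ratio of covered bases between 1.736 and 2.008 when 1 library was left out. Both stayed within 1 SD (0.379 and 0.336) of 1.773 and 1.852 under the other alternatives. For the peak ratio this says little about the processing. Keeping the same part of every list could not move it, and the block only averaged the same peak numbers in another way. Merging touching peaks and requiring 50% of the shorter of region and peak could move nothing. The difference in similarity moved to 0.169 without control replicate 3 (0.088 to 0.169 over all libraries left out).

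Regions called only in knockdown numbered 12157. There were 6701 with the stronger part of each list, 2628 with equal lists by score, 1894 with random thinning and 30254 when 2 of 3 libraries sufficed. Random thinning removes more of the longer knockdown lists, so its counts say nothing of direction. Regions called only in control numbered 207, and 1113, 2761 and 1326 with equal lists, random thinning and 2 of 3 libraries. With 1 library left out the counts ran from 13999 to 23412 for knockdown and from 253 to 801 for control. Fewer libraries then had to meet the condition, which by itself does not explain why the count depended on the library left out. Other causes were not tested.

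Against 571 bins higher and 292 lower, there were 2564 and 20 without scaling, 305 and 446 scaled to the median ratio, 893 higher by bases covered, 369 and 186 with equal lists, and 155 and 307 with equal lists and median scaling. Leaving out 1 library gave 135 to 703 higher and 159 to 316 lower; the cause was not tested. Of 278 values of the named bins under alternatives, 274 stayed under the threshold, 4 did not and 0 reversed. The bins were picked as the largest called changes in the same counts, and some settings could not change their estimates. Values that could not be tested are not among the 278. The count is therefore weak support for these bins. The 4 were the bins on chromosomes 14 and 18 with equal lists. That on chromosome 14 moved from -1.96 to -4.00 relative to the median (limma adjusted p = 0.0657), and that on chromosome 18 from -1.95 to -0.64 (adjusted p = 0.463). With equal lists 10 of the 20 named bins, 8 of them rises, had too few peaks for a test, and 7 of the other 10 moved over 1.5-fold, as did 9 of 20 with a pseudocount of 1.

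With the replicate number as a block, 655 bins were higher and 308 lower, the peak ratio was 1.777 and that of bases 1.854. Libraries of the same number correlated by 0.03, 0.11 and 0.09 in their deviations from the group means. Not every library correlated best with its own number, as control replicate 1 reached 0.04 with knockdown replicate 2. Whether the numbers pair the samples cannot be told from such small values. Promoter share, gene lists, repeat share, motifs and counts near gene starts were not run. Depth is unknown and limits every count.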

Other observations

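The tests of explanations in this part were all chosen after the results were seen, and the bounds of some were set again after their values were known. The share of a library's peaks on chromosome 19 was 5.04 ± 0.207% in control and 3.62 ± 0.176% in knockdown (SD, n = 3 each), and on chromosome 18 it was 1.83 ± 0.052% and 2.24 ± 0.017%. The groups did not overlap on 17 of 23 chromosomes, 7 lower and 10 higher in knockdown, where chance gives 10% for a single chromosome. The shares of a library depend on each other, so this count is not a test. The smallest adjusted p was 0.135 by the exact permutation test. For every 100 regions called in all 6 libraries, chromosome 18 had 68.4 regions called only in knockdown, chromosome 13 had 61.5 and chromosome 19 had 14.0. With lists of equal length, the ratio of shares was 0.83 for chromosome 19 and 1.162 for chromosome 18. The lowest ratio was then that of chromosome 21, at 0.666 (0.81 as deposited).

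Regions called only in knockdown outnumbered those called only in control by 58.73 times (12157 against 207). With lists of equal length by score the ratio was 2.36 (2628 against 1113) and ran from 1.67 to 3.15 when 1 library was left out, so most of the excess went with list length. A ratio above 1 does not decide on list length alone. The equal lists held the strongest 43.8 to 57.7% of the knockdown lists but 74.2 to 100% of the control lists. Agreement was then higher among knockdown libraries (mean Jaccard index 0.644) than among control libraries (0.528). Both counts by score exceeded the highest of the mixed choices of 3 libraries, 593, but with 10 splits of the libraries a share under 0.05 cannot be reached. Depth or signal over background may account for the pattern, since the lowest knockdown library had 1.286 times the peaks of the highest control library and such a property cannot be told apart from the knockdown. A biological opening of these sites also stays open.

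Bins lower in knockdown gathered beside the longest stretches without a peak, with 67 of 292 (22.95%) in the flanks against 157 of 2856 tested bins (5.5%; Fisher's exact test, odds ratio 8.17, p = 2.88e-28; bins are not independent replicates). Under the flank definition used first, these were 65 of 292 (22.26%) and 169 of 2856 (5.92%), with an odds ratio of 6.77 and p = 2.85e-24 by Fisher's exact test. By the second definition, the flanks held 7.31, 7.52 and 5.89% of all peaks in control replicates 1, 2 and 3, and 4.33, 4.89 and 4.54% in knockdown. The share was lowest in the longest list of each group. With lists of equal length, 48 of 186 lower bins (25.81%) lay in the flanks, against 5.56% of tested bins. Depth as a cause could not be tested. Sequence beside these stretches is argued against as the whole cause of the lower shares, since 225 of the 292 lower bins lay outside the flanks. Of these, only 15 had fewer peaks in knockdown. A fit of the 2699 bins outside the flanks alone called 229 lower (231 of 2687 with the definition used first). It used the same counts and library totals, so it is not a separate test. As the whole cause of lost peaks, sequence beside these stretches stays open. Of the 20 bins lower without scaling, 3 lay outside the flanks (4 with the definition used first). Only chromosome 14:106000001-107000000 did so by both definitions with groups that did not overlap (limma adjusted p = 0.0001, or 0.123 by Bonferroni). Of the 67 flanking lower bins, 17 were lower without scaling too, while peaks in the other 50 had a ratio of 1.002 ± 0.133 (0.894 over all 67 and 1.191 over all flanks), so that a loss and a smaller gain than elsewhere cannot be told apart in these 50, and neither repeat mapping nor a biological cause was tested.

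The same flanks held 55 of the 207 regions called only in control (26.57%), 301 of the 12157 called only in knockdown (2.48%) and 1532 of the 28749 called in all 6 libraries (5.33%). Under the definition used first, the shares were 26.09%, 2.71% and 5.32%.

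Control replicate 3 was the control library nearest to knockdown, and with lists of equal length its Jaccard index with knockdown libraries was 0.533 to 0.561 (mean 0.551), above the mean of 0.527 with the other control libraries (0.538 and 0.516). That of control replicates 1 and 2 with knockdown was 0.438 to 0.487, a gap of 0.087 between the means (0.080 as deposited). Equal length kept 74.2% of the list of control replicate 3, against 100 and 94.5% for control replicates 1 and 2. The gap therefore does not decide on list length alone. Of regions in 2 knockdown libraries and in neither other control library, control replicate 3 called 42.1 to 48.6% at equal length. The left-out knockdown library called 67.6 to 80.2% of the same regions (30.2 to 37.9% against 61.4 to 88.3% as deposited). Of regions in both other control libraries and in neither of 2 knockdown libraries, it called 36.5 to 39.0% against 9.0 to 14.9% (28.3 to 34.5% against 10.6 to 33.9% as deposited, higher on each set). These shares of regions argue against a wrong label, while a mixed sample or a control library of other quality stays open.

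The 863 bins called between the groups compare with a highest value of 0 for the other splits of the 6 libraries, and 1 of the 10 splits, the real one, gave as many. Every other split mixed control and knockdown libraries, so that any difference between the groups, list length included, entered its spread and lowered its calls. The 0 is therefore no support for the 863. With 10 splits, a share under 0.05 cannot be reached.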
